A study of Mus musculus with 2 samples.

How the data were processed

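Bone marrow stromal cells (BMSCs) are the plastic-adherent fraction of flushed marrow, which holds mesenchymal cells able to form bone and fat together with adherent blood cells. Marrow of femurs and tibias of C57BL/6J mice was plated in alpha-MEM with 10% fetal bovine serum, and cells that had not attached were washed off 48 h later, per the labels' protocols. No osteogenic medium was given, per the labels. One library came from mice with floxed Slc31a1 and no Cre (WT) and one from littermates that also carried Prrx1-Cre (cKO), a driver active in limb mesenchyme. Both libraries were made with the 10x Genomics Chromium 3' kit, which captures mRNA near its polyadenylated end and tags each molecule with a unique molecular identifier (UMI).

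The deposited matrices held raw UMI counts per gene and barcode, written by Cell Ranger 7.1.0, per the file headers. The genome build was mm10 (GRCm38), per the submitters' processing notes, which also name Seurat. Whether intronic reads were counted is not given in the sources used here. The barcodes had already been called as cells, and the lowest total was 500 UMIs in both libraries. Of 32285 gene identifiers in the files, 32235 were found in the GENCODE M21 annotation of GRCm38, from which gene coordinates (1-based) were taken. The authors' cell annotation was not used here, so cell classes were rebuilt from the counts.

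Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which left 8171 of 9125 WT barcodes and 5506 of 6140 cKO barcodes. Scrublet, run per library, marked 2 cells in each library at its automatic threshold, 0.0245% of WT and 0.0363% of cKO cells, so that threshold had not worked. By a fallback set beforehand (0.8% per 1000 cells), the 534 WT and 243 cKO cells with the highest scores were removed. This left 7637 WT cells and 5263 cKO cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered together by Leiden (resolution 0.5, 15 neighbours) with scanpy 1.11.5 and leidenalg 0.10.2. Mesenchymal-like cells were re-clustered with the same settings. No batch correction was applied.

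Markers were fixed before the data were examined. The scoring rule for names was set after a first look at the clusters. A cluster took the class whose markers lay furthest above the mean of the clusters when at least 3 markers were 2-fold above that mean (1.5-fold for mesenchymal states). It stayed unnamed when another class had more markers among its 10 leading genes, or when its cells were shallow and none of its markers was among them; a mesenchymal state also needed 1 marker there.

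With 1 library per group no test across samples exists, and no p-value is given. UMIs were summed per library and cell class and expressed as CPM, the standard scaling of counts by the total UMIs of that library and class. Ratios are cKO over WT, with exact conditional binomial 95% intervals. Levels have exact Poisson intervals and shares have exact Clopper-Pearson intervals. All intervals cover counting error only, compare these 2 libraries and not the genotypes, and leave out differences between mice, cultures and captures. Log2 ratios used a prior of 1 CPM. For each of 30 gene lists fixed beforehand, the median log2 ratio was taken over members with at least 10 CPM in either library and placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Shares of cells with a G2 or M phase signature (UMIs of at least 3 list genes) were computed after thinning each cell to 3018 UMIs, the 10th percentile of mesenchymal-like cells, and shares of cells with a given UMI after thinning to 20000.

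Genes were named by a rule fixed beforehand: among genes with at least 50 CPM in either library in mesenchymal-like cells, without mitochondrially encoded, ribosomal protein, haemoglobin and predicted genes, the 15 highest and 15 lowest ratios; Slc31a1 and Prrx1; and up to 4 members per list with the largest absolute log2 ratio. Not every gene the rule picks is named in the text. Other genes in the text were chosen after their values were seen. Alternatives covered the cell filter, doublets, clustering resolution, centring within library, cells with a Prrx1 UMI in place of the clusters, equal weight per cell, other scalings, the filter on low list members and the prior. A restriction to mesenchymal-like cells with at least 20000 UMIs, and re-clustering without the pre-osteoblast markers, were added after the data were seen.

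The ratio step was tested on simulated counts drawn from the pooled mesenchymal-like means at the totals of the 2 libraries, over 8805 genes of which 200 were changed, 50 at each size. The intervals held the true ratio for 95.1% of 8605 unchanged genes, 98% of genes at 1.1-fold, 92% at 1.5-fold, 92% at 2-fold and 100% at 0.5-fold. The counts were independent Poisson draws, the model that the intervals assume. This checks the calculation only, and variation between cells was not simulated. The list step was tested on the observed gene ratios. Of 100 unshifted lists of 15 genes, 1 fell outside the central 95% of random lists, and all 100 lists shifted by 0.2 on the log2 scale lay above it. The unshifted lists were drawn at random from the same genes as the reference lists, so this also checks the calculation only. Lists of genes that vary together were not simulated, and such lists may leave the central 95% more often.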

Results

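Single-cell transcriptomes of adherent marrow cells were compared between 1 WT and 1 cKO library, to ask how loss of the copper importer SLC31A1 in the mesenchymal lineage alters stromal and osteogenic composition and expression. The WT library held 152398639 UMIs in 9125 barcodes (median 7919) and the cKO library 126031142 UMIs in 6140 barcodes (median 8217). After filtering, 7637 WT and 5263 cKO cells remained, with medians of 9706 and 9710 UMIs. There were no replicates, so every difference is between these 2 libraries and has no replicate check.

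Slc31a1, the targeted gene, was lower in mesenchymal-like cells of the cKO library and at a similar level in both libraries in macrophage-like cells, which the Prrx1-Cre driver is not aimed at. In mesenchymal-like cells it had 42.4 CPM in WT (95% interval 41.1 to 43.6; 4390 UMIs) and 14.3 CPM in cKO (13.5 to 15.2; 1192 UMIs), a ratio of 0.338 (0.317 to 0.361). In macrophage-like cells the levels were 70.1 CPM in WT and 72.3 CPM in cKO, a ratio of 1.03 (0.967 to 1.1). The mesenchymal ratio was 0.328 times the macrophage ratio (0.299 to 0.359). The 3 larger mesenchymal clusters gave ratios of 0.399, 0.344 and 0.349. Slc31a1 (ENSMUSG00000066150) lies on chromosome 4 from 62360727 to 62391769 on the plus strand of GRCm38 and overlaps Cdc26 on the other strand. The labels do not say which exons are floxed, and a 3' UMI outside the deleted part need not be lost.

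With mesenchymal-like cells thinned to 20000 UMIs, 56.7% of 1682 WT cells (54.3 to 59.1) and 24.1% of 1135 cKO cells (21.6 to 26.6) held a Slc31a1 UMI. The unthinned shares were 52.5% and 46.9%, at medians of 13912 UMIs in WT and 61899 UMIs in cKO, and thinning left out 2045 WT and 280 cKO cells. At 20000 UMIs, 68.5% of 295 WT and 71.1% of 190 cKO macrophage-like cells held a UMI (unthinned 45.3% and 41.6%, at medians of 9204 and 7681 UMIs; 2516 and 2337 cells were left out), and neutrophil-like cells had 23.6 CPM and 25.2 CPM, above the cKO mesenchymal level. No class known to lack the gene was measured, so no background share of cells with a UMI is given. Prrx1, the gene whose enhancer drives the Cre, stood at 457 CPM and 450 CPM in mesenchymal-like cells (ratio 0.986, 0.972 to 0.999), a difference whose sign depends on the scaling.

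**Figure D1:**
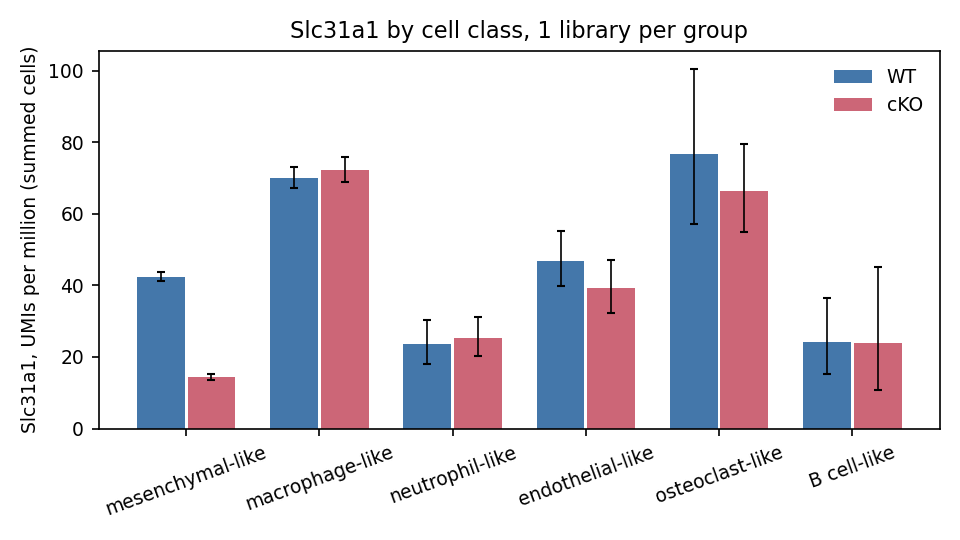
Slc31a1 in summed cells of each class, in CPM, with exact Poisson 95% intervals; blue bars are WT and red bars cKO, 1 library each. The bars differ most in mesenchymal-like cells, 42.4 against 14.3, while macrophage-like cells stand at 70.1 and 72.3.

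Clusters formed mesenchymal-like, macrophage-like, neutrophil-like, endothelial-like, osteoclast-like, B cell-like, T or NK cell-like and megakaryocyte-like classes. Mesenchymal-like cells made up 48.8% of WT cells (47.7 to 49.9; 3727 cells) and 26.9% of cKO cells (25.7 to 28.1; 1415 cells). Most of the difference lay in cells of low depth. Those under 20000 UMIs made up 26.8% of WT cells (2045) and 5.32% of cKO cells (280), whereas those with at least 20000 UMIs made up 22.0% (21.1 to 23.0; 1682 cells) and 21.6% (20.5 to 22.7; 1135 cells). Without cluster 1, the main cluster of low depth, and with it also left out of the total, 31.2% of WT cells and 23.8% of cKO cells were mesenchymal-like (difference -7.43 points, -9.12 to -5.73), and among cells with at least 20000 UMIs 80.0% and 77.1%. Most WT mesenchymal-like cells were in cluster 1 (52.3%, against 212 of 1415 cells in cKO; median 5453 and 3673 UMIs), whose leading genes were Igfbp5, Mmp13 and Col1a1, and most cKO cells in cluster 2 (57.7%, against 35.0% in WT; median 63927 and 46360 UMIs).

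Macrophage-like cells were 36.8% of WT (35.7 to 37.9) and 48.0% of cKO cells (46.7 to 49.4). Neutrophil-like cells were 4.10% and 6.35%. Osteoclast-like cells, led by Acp5, Mmp9 and Ctsk, were 0.419% of WT cells (0.287 to 0.591; 32 cells) and 1.56% of cKO cells (1.24 to 1.93; 82 cells). Endothelial-like cells were 1.61% and 1.63%. B cell-like cells were 2.06% and 1.20%, and of these an immunoglobulin-rich cluster led by Igkc, Igha and Jchain held 111 WT and 6 cKO cells; the B cell-like class also carried 151 CPM of Prrx1 in WT and 7.93 in cKO, whereas osteoclast-like cells had 7.37 and 67.5 CPM and endothelial-like cells 24.1 and 87.6 CPM. T or NK cell-like cells were 0.615% and 0.722%, and megakaryocyte-like cells 0.144% and 0.152%. Of the unnamed clusters, cluster 7, which scored nearest to mesenchymal and was led by H19, held 2.15% of WT and 7.33% of cKO cells, with medians of 2679 and 2357 UMIs and mitochondrial shares of 0.25% and 0.182%. Unnamed cluster 9 held 0.903% and 2.87%, cluster 8, with Ccr2 and class II genes, 1.89% and 2.62%, and cluster 17 held 0.511% and 0.665%. Shares of all cells move together, so a larger mesenchymal-like share in WT lowers every other share.

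**Figure D2:**
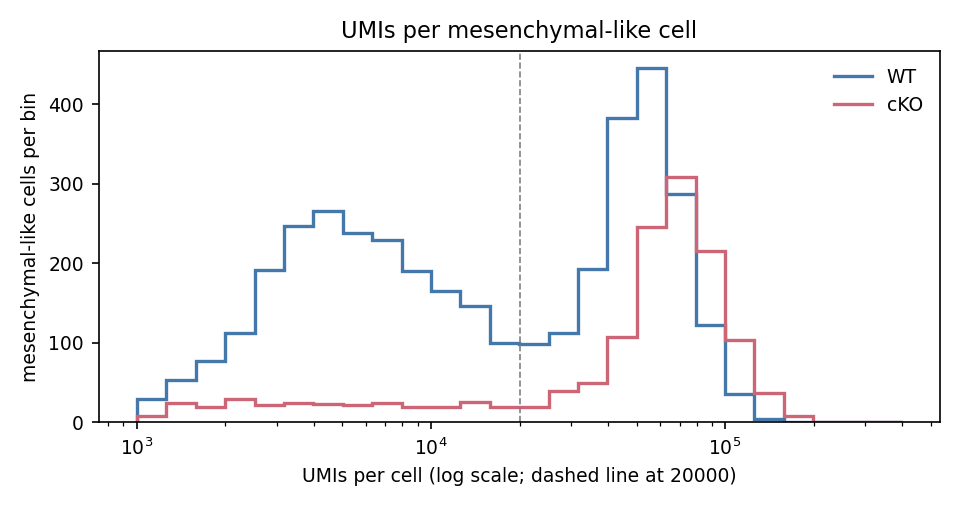
Number of mesenchymal-like cells by UMIs per cell (log axis) in the WT library (blue) and the cKO library (red), with a dashed line at 20000 UMIs. WT has 2045 cells left of the line against 280 in cKO, and 1682 against 1135 to the right of it.

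Re-clustering mesenchymal-like cells, which addresses the step from stromal states towards pre-osteoblasts, gave a pre-osteoblast-like cluster led by Fat3, Ibsp and Slc13a5. It held 318 WT cells, 8.53% of mesenchymal-like cells (7.65 to 9.48), and 316 cKO cells, 22.3% (20.2 to 24.6). With no cell filter the shares were 4.72% and 7.97%, and with the stricter filter 6.58% and 8.38%. Without the pre-osteoblast markers in the re-clustering, an alternative added after the data were seen, the shares were 17.5% and 33.7%. Among cells with at least 20000 UMIs, also added afterwards, they were 18.5% (16.7 to 20.4) and 25.7% (23.2 to 28.4). At a Leiden resolution of 1.0, where the mesenchymal-like class held 2712 WT and 1298 cKO cells, they were 5.94% and 5.62%, and among 4270 WT and 2082 cKO cells with a Prrx1 UMI 6.04% and 5.67%. Neither of these differences was larger than counting error.

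**Figure D3:**
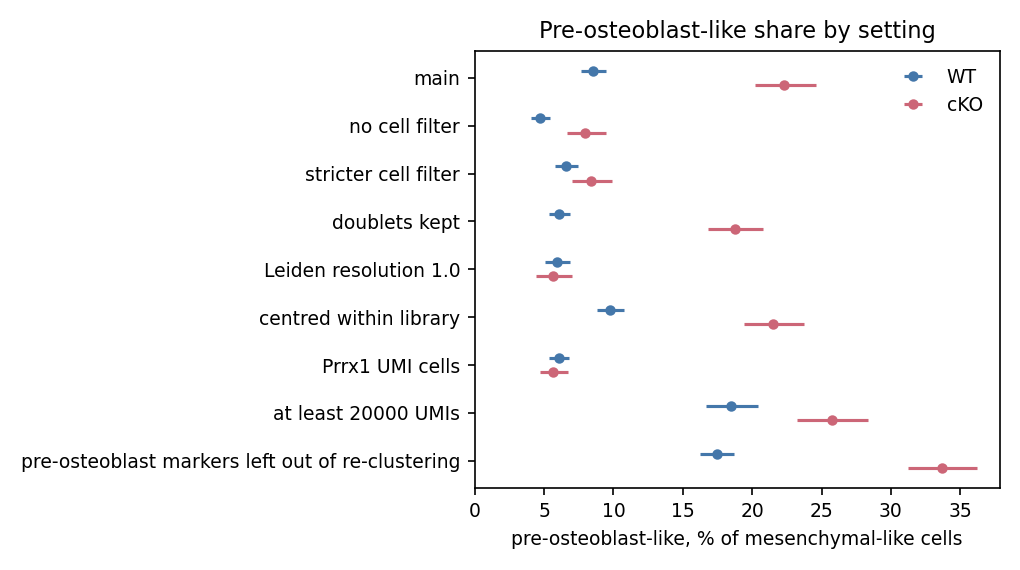
Pre-osteoblast-like cells as a percentage of mesenchymal-like cells under each setting, with exact 95% binomial intervals; blue points are WT and red points cKO. The main shares are 8.53% and 22.3%, and the points overlap at a Leiden resolution of 1.0 and among cells with a Prrx1 UMI.

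A cycling-like cluster held 491 WT (13.2%) and 378 cKO (26.7%) mesenchymal-like cells, at medians of 61286 and 72673 UMIs. The many shallow WT cells lower its WT share. Unnamed clusters 0, 2 and 6, described below, also scored nearest to cycling, with 13, 5 and 8 of its markers above the threshold. No cycling marker was among their 10 leading genes, so they stayed unnamed and the cycling-like share leaves their cells out. Each held a larger share of WT than of cKO cells. Of all cells, the cluster led by Prc1, Anln and Hmmr before re-clustering held 6.05% in WT and 6.95% in cKO. A stromal progenitor-like cluster led by Sfrp1 and Pdzrn4 held 20 WT cells, at a median of 6188.5 UMIs, and 0 of 1415 cKO cells (upper limit 0.260%). Under 20000 UMIs, cKO had only 280 mesenchymal-like cells against 2045 in WT. Unnamed clusters 0 and 2, of low depth and led by neutrophil or immunoglobulin transcripts such as Ngp and Iglc1, held 31.4% and 22.4% of WT cells and 13.5% and 3.89% of cKO cells. Unnamed cluster 1, led by Pde3a and Cxcl14, held 20.2% and 32.5%. Unnamed clusters 5 and 6 held 2.07% and 1.64% of WT cells and 0.777% and 0.283% of cKO cells.

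A G2 or M phase signature was found in 53.6% of 3309 WT (51.9 to 55.3) and 36.8% of 1319 cKO mesenchymal-like cells (34.2 to 39.4) thinned to 3018 UMIs. Unthinned, the shares were 86.2% and 86.3%; thinning left out the shallower cells. At the same thinned depth, cells under 20000 UMIs gave 71.9% in WT (69.7 to 74.1; 1627 cells) and 47.8% in cKO (40.4 to 55.3; 184 cells), and deeper cells 35.9% (33.6 to 38.2) and 35.0% (32.2 to 37.8). T or NK cell-like cells, thinned alike, gave 2 of 40 cells in WT and 0 of 36 in cKO, neutrophil-like cells 51.4% and 50.5% and macrophage-like cells 31.7% and 36.4%. Free RNA stays open as a source of this signature in shallow cells, many of which lay in clusters led by neutrophil transcripts. Neutrophil markers made up 0.233% of UMIs in shallow WT and 0.0894% in shallow cKO mesenchymal-like cells. In neutrophil-like cells S100a9 alone had 89603 CPM in WT and 95935 CPM in cKO. The shallow WT share also lay above that of neutrophil-like cells (45.4 to 57.4), while in cKO the intervals overlapped. These values argue against neutrophil RNA as the main source in these libraries.

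Within mesenchymal-like cells, the genes with the lowest ratios fell into 2 kinds. H19, an imprinted long non-coding RNA, had 62.1 CPM in WT and 23.9 CPM in cKO (ratio 0.385, 0.366 to 0.405). Serping1, encoding the C1 inhibitor, had a ratio of 0.454 (0.431 to 0.479), the collagenase gene Mmp13 0.507 (0.489 to 0.527), Igfbp5 0.519 (0.510 to 0.529), Aldh1a2, which makes retinoic acid, 0.564 (0.541 to 0.588), Ogn 0.588 (0.575 to 0.602), Lifr 0.607 (0.589 to 0.625) and Cpne8 0.613 (0.587 to 0.640). All 8 stayed between 0.366 and 0.613 among cells with at least 20000 UMIs. The other 7 were Ngp (0.323), S100a8 (0.330), S100a9 (0.370), Pf4 (0.406), Apoe (0.456), Lyz2 (0.513) and Fcer1g (0.543), transcripts with far higher levels in blood cells. S100a9, for example, had 230 CPM and 85.1 CPM in mesenchymal-like cells against 89603 CPM and 95935 CPM in neutrophil-like cells. The ratio of Ngp was 0.536 among cells with at least 20000 UMIs.

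Highest in cKO were S100a4, a calcium-binding protein gene of fibroblasts and macrophages, with 162 CPM and 358 CPM (ratio 2.21, 2.17 to 2.26), and the prostaglandin synthase gene Ptgs2, with 43.1 CPM and 87.6 CPM (ratio 2.03). Nav2 (1.75), Hmga2 (1.66), Sgk1 (1.6), Cxcl14 (1.58), Phlda1 (1.58), Ank (1.56), a gene for pyrophosphate transport, and Pcdh7 (1.54) followed. Also among the 15 highest were the BMP antagonist gene Grem1 (1.51), Tnn (1.5), the immediate early gene Egr1 (1.49), Ecm1 (1.48) and the haem oxygenase gene Hmox1 (1.45). In macrophage-like cells S100a4 (230 CPM and 451 CPM) and Hmox1 (1.44) were also higher, and Nav2 had 0.916; mesenchymal transcripts such as Tnn (13.1 CPM and 21.3 CPM) were at trace levels there, at which free RNA was not excluded. In the pre-osteoblast-like cluster Cxcl14 had a ratio of 0.392.

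**Figure D4:**
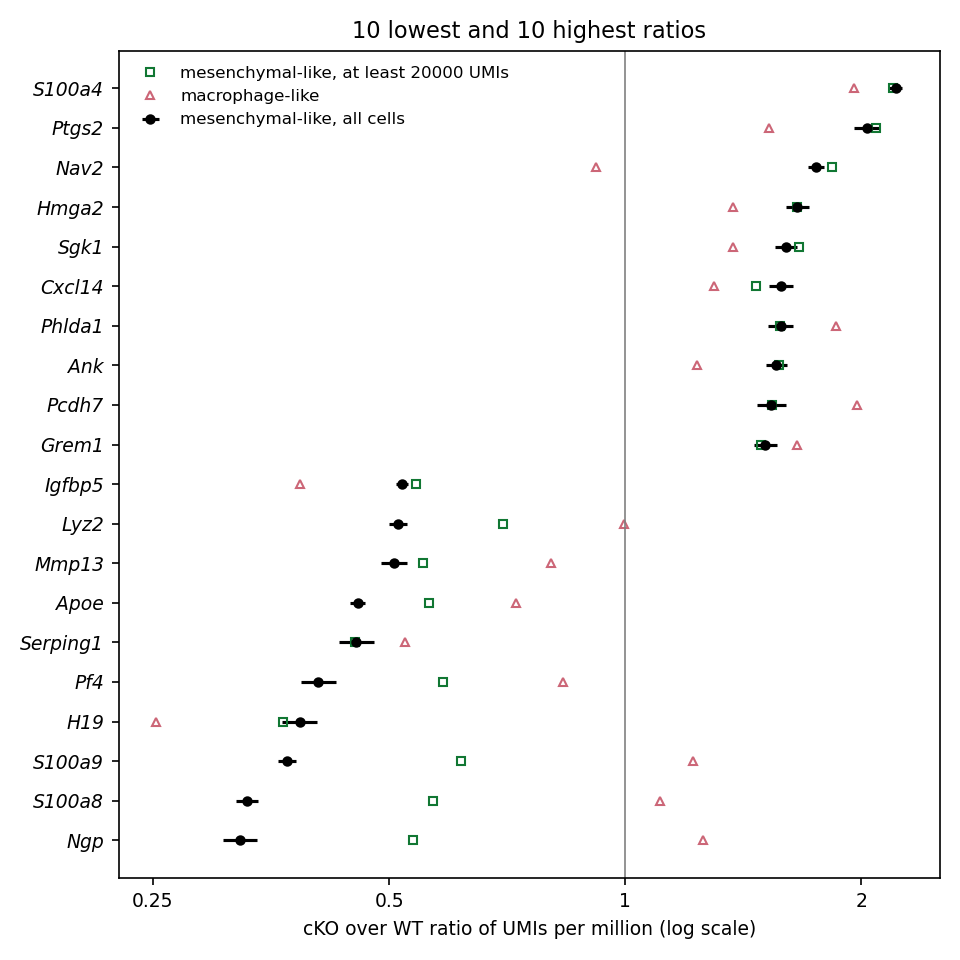
Ratio of CPM, cKO over WT (log axis), for the 10 lowest and 10 highest genes in mesenchymal-like cells: black points with exact 95% intervals for all mesenchymal-like cells, green squares for those with at least 20000 UMIs and red triangles for macrophage-like cells. S100a4 is highest at 2.21 and Ngp lowest at 0.323.

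Osteoblast differentiation genes were slightly lower in cKO mesenchymal-like cells. Of 18 measured members, 6 were higher and 12 lower, with a median log2 ratio of -0.10 at percentile 0.92 of random lists. Only Bmp4 differed by at least 1.5-fold, with a ratio of 0.489 (0.452 to 0.528). Smpd3 had a ratio of 0.773, whereas Sp7, a transcription factor needed for osteoblasts, had 1.35 (1.29 to 1.40) and Spp1, encoding osteopontin, 1.30 (1.30 to 1.31). Among cells with at least 20000 UMIs the median was -0.04, at percentile 13.6. In clusters 0, 1, 3 and 4 it was 0.00, -0.06, -0.02 and -0.10, at percentiles 57.9, 2.24, 36.0 and 1.26. In cluster 4, the pre-osteoblast-like one, 16 of 22 members were lower, 6 of them by at least 1.5-fold. There 6 members were higher, 1 of them, Spp1 (1.76), by at least 1.5-fold. Over all mesenchymal-like cells macrophage and neutrophil markers also differed, with medians of -1.0 over 15 genes and -1.43 over 6 genes; among cells with at least 20000 UMIs these were -0.58 and -0.68. By cluster (0, 1, 3 and 4) they were -0.11, -0.54, -0.47 and -0.58 for macrophage markers and -1.38, -0.00, 0.30 and 0.05 for neutrophil markers, of which 3 or 4 reached 10 CPM in the last 3 clusters.

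Marrow stromal progenitor genes were lower in cKO, with 5 of 21 members higher, 16 lower and a median of -0.17, below all 10000 random lists. Igfbp5 had a ratio of 0.519, Hp of 0.576 (0.548 to 0.605) and the transcription factor gene Ebf3 of 0.702 (0.679 to 0.726), against 1.51 for Grem1. The median was -0.16 among cells with at least 20000 UMIs and -0.16, -0.00, -0.10 and -0.27 in re-clustered clusters 0, 1, 3 and 4, those with at least 100 cells of each library. In macrophage-like cells, where 12 members reached 10 CPM, it was -0.09 at percentile 15.8.

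Copper transport and chaperone genes other than Slc31a1 differed little. Of 20 measured members, Slc31a1 included, 13 were higher and 7 lower in cKO, with a median of 0.04 at percentile 96.5, and Slc31a1 was the only member to differ by 1.5-fold. The metallothionein gene Mt2 had a ratio of 1.35 (1.30 to 1.40) and Steap2, a metalloreductase gene, 1.19 (1.14 to 1.25), against 0.749 (0.707 to 0.793) for Cp, which encodes ceruloplasmin. Mt2 had a ratio of 1.61 in macrophage-like cells. Copper-dependent enzymes had a median of -0.10 at percentile 4.05 (2 of 12 higher), with Loxl3 at 1.22, Loxl1 at 0.911 and Sod3 at 0.849, and cuproptosis and lipoylation genes 0.02 at percentile 88.6, with Fdx1 at 1.13, Gcsh at 1.09, Cdkn2a at 1.06 and Dbt at 0.933.

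Nuclear genes of complex IV, a copper enzyme of the respiratory chain, were slightly higher in cKO mesenchymal-like cells, with 17 of 22 members higher, none by 1.5-fold, and a median of 0.06 at percentile 98.2. Cox6b1 had a ratio of 1.13 (1.12 to 1.15), Coa6 1.13, Coa3 1.1 and Cox18 1.09. Complex I genes had a median of 0.07 at percentile 99.98 (26 of 37 higher; Ndufb2 1.15), and complexes III and V 0.05 at percentile 96.6 (19 of 25 higher; Cycs 1.14). With at least 20000 UMIs these medians were 0.05 and 0.02, at percentiles 99.8 and 85.8. In clusters 0, 1, 3 and 4 the complex I median was -0.05, 0.02, 0.06 and 0.02, at percentiles 12.1, 84.8, 99.9 and 91.9. That of complexes III and V was -0.04, 0.01, 0.02 and 0.01, within the central 95% in each. In macrophage-like cells 28 of 37 complex I genes were lower (median -0.06). Mitochondrially encoded genes had a median of 0.09 at percentile 98.9, with mt-Cytb at 1.26 and mt-Nd4l at 0.774, and a median of -0.08 with each cell weighted equally. With at least 20000 UMIs the median of this list was 0.16, above all random lists, with 10 of 13 members higher. By cluster (0, 1, 3 and 4) it was 0.26, 0.15, 0.11 and 0.06, at percentiles 100, 99.99, 99.96 and 94.6. Macrophage-like cells gave -0.03. Among cells with at least 20000 UMIs the complex IV median was 0.03, at percentile 94.6, and in macrophage-like cells it was -0.01. In clusters 0, 1, 3 and 4 it was -0.03, -0.01, 0.04 and 0.04, within the central 95% of random lists in each.

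The BMP response list had the highest median in cKO mesenchymal-like cells, 0.34, above all 10000 random lists, with 9 of 11 members higher. Id1 had a ratio of 2.51 (2.37 to 2.65) and Id3 of 1.39 (1.37 to 1.42). Immediate early genes had a median of 0.34, also above all random lists, with 14 of 18 higher, including Egr3 (2.02), Nr4a1 (1.90) and Dusp1 (1.44). The antioxidant response had a median of 0.17, likewise above all random lists, with 11 of 16 higher, including Srxn1 (1.37), Gclm (1.28) and Gpx1 (1.19). In clusters 0, 1, 3 and 4 the BMP median was 0.52, 0.38, 0.43 and 0.52, and the antioxidant median 0.20, 0.18, 0.13 and 0.24. All 3 lists were also higher in macrophage-like cells, with medians of 0.92, 0.15 and 0.38.

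The osteoclast support list, which also holds inhibitors of osteoclast formation such as Sema3a, had a median of 0.33 over 6 members, above all random lists, with Ccl2 at 1.47 (1.37 to 1.58), Csf1, the macrophage growth factor gene, at 1.41 (1.39 to 1.43), Sema3a at 1.30 and Tnfsf11, encoding RANKL, at 1.25 (1.18 to 1.33). Resampling the members of the osteoclast support list gave an interval of -0.10 to 0.51 for its median. Inflammatory and secreted factors had a median of 0.20 at percentile 99.99 over 8 members that went both ways, from Ptgs2 (2.03) and Ccl7 (1.51) to Mmp13 (0.507) and Lcn2 (0.386), a neutrophil transcript. Both lists were also higher in macrophage-like cells. Their medians there were 0.37 over 3 members and 0.25 over 9, at percentiles 99.86 and 99.97. TGF-beta and myofibroblast genes had a median of 0.08 at percentile 99.0, with 11 of 17 members higher and 6 lower, and 9 and 8 among cells with at least 20000 UMIs; Smad7 had 1.33, Ccn1 1.28, Tgfbi 1.22 and Ccn2 1.21. Heat shock genes had 0.09 at percentile 98.0, with 10 of 11 higher, among them Hspb1 (1.28), Hspa1b (1.19), Cryab (1.17) and Hsph1 (1.1), but 0.05 at percentile 91.5 among cells with at least 20000 UMIs, and the list lay within the central 95% in each of clusters 0, 1, 3 and 4. The chondrocyte list had 0.20 over 4 members, with Sox9 at 1.44 and Col11a1 at 0.785.

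Lower in cKO were hypoxia response genes, with 11 of 13 members lower and a median of -0.17 at percentile 0.04. Bnip3 had a ratio of 0.736 (0.717 to 0.755), Pdk1 of 0.782 and the glucose transporter gene Slc2a1 of 0.825, against 1.23 for Vegfa. Glycolysis genes had a median of -0.10 at percentile 0.89 (14 of 16 lower; Hk1 0.839, Pfkfb3 0.865), and shared Pdk1 and Slc2a1 with that list. All 6 measured interferon response genes were lower, with a median of -0.24 at percentile 0.18, including Bst2 (0.700), Stat2 (0.780) and Gbp2 (0.860). Collagen matrix and crosslinking genes had a median of -0.07 at percentile 0.19 (25 of 33 lower), with Col8a1 at 0.737, Col3a1 at 0.754 and Fbn1 at 0.772, and Timp1 at 1.30. In macrophage-like cells the medians of the hypoxia, glycolysis and interferon lists were -0.06, 0.08 and -0.11, at percentiles 36.6, 94.0 and 14.9.

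Over all mesenchymal-like cells together, the remaining lists lay within the central 95% of random lists. These were adipocyte differentiation (median 0.03; Apoe 0.456, Fabp4 1.34, Cebpb 1.34, Lpl 0.751), integrated stress response (0.01; Gdf15 1.40, Slc7a5 1.17, Aldh1l2 0.876), endoplasmic reticulum stress (0.01; Manf 1.14, Sdf2l1 1.12, Creld2 1.11, Sel1l 0.920) and p53 targets and senescence (0.04; Btg2 1.25, Eda2r 1.25, Mdm2 1.23, Cdkn1a 1.21). They also included Wnt response (0.01; Wnt5b 1.34, Sfrp1 0.858, Fzd1 1.15, Nkd2 0.880), G2 and M phase (-0.08; Top2a 0.798, Nusap1 0.820, Prc1 0.864, Mki67 0.868), S phase (-0.01; Rrm2 1.26, Pola1 0.885, Chaf1b 0.885, Fen1 1.12) and iron handling (0.05; Trf 0.684, Ftl1 1.19, Fth1 1.18). Of these 8 medians, each but that of G2 and M phase changed sign under at least 1 alternative. In clusters 0, 1, 3 and 4 the G2 and M phase median was -0.23, 0.44, -0.09 and 0.11, at percentiles 0, 100, 0.3 and 85.4, and the S phase median -0.20, 0.00, 0.06 and 0.19, at percentiles 0.05, 42.4, 99.1 and 99.9. Other lists of this group also left the central 95% in single clusters. In cluster 4, Wnt response had -0.15 at percentile 1.4 (12 of 16 lower) and adipocyte differentiation -0.16 at percentile 0.87. In cluster 0, p53 targets and senescence had 0.15 at percentile 99.8. Iron handling had 0.13 and 0.12 in clusters 0 and 3, at percentiles 98.3 and 99.5. Sex chromosome genes and the markers of B cells, endothelial cells, erythroid cells and osteoclasts had fewer than 3 members at 10 CPM, so no median was taken.

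**Figure D5:**
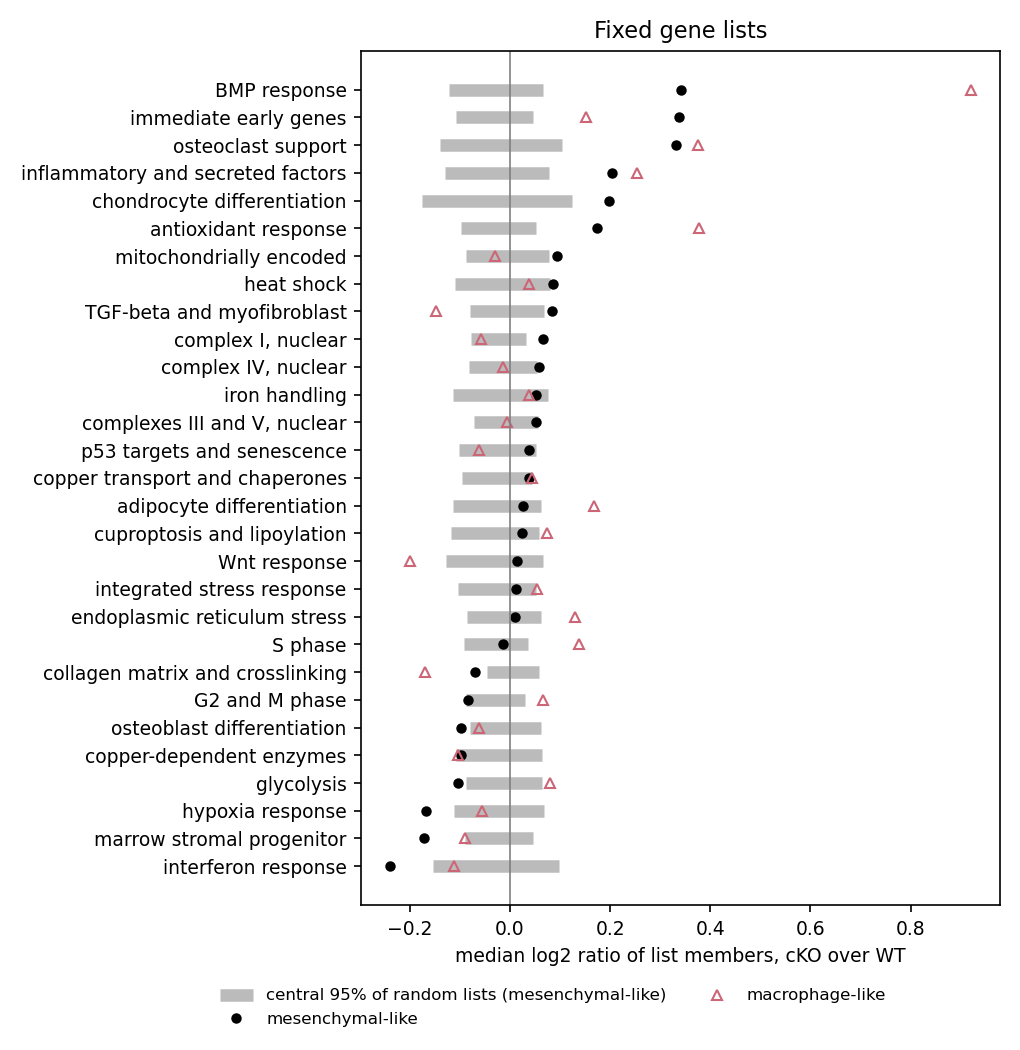
Median log2 ratio, cKO over WT, of each fixed gene list in mesenchymal-like cells (black points) and macrophage-like cells (red triangles); grey bars span the central 95% of matched random lists in mesenchymal-like cells. BMP response lies highest in both classes, at 0.34 and 0.92, and interferon response lowest in mesenchymal-like cells, at -0.24.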

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

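The restriction to cells with at least 20000 UMIs and the re-clustering without pre-osteoblast markers were chosen after the data were seen. Of 82 alternative values for the main comparisons, 63 lay within the main interval (for lists, the interval from resampling members), 16 moved and 3 reversed, a word kept for a change of sign of a value whose interval excluded no difference; of 310 for named genes, 92 moved and 3 reversed, and of 324 for other lists, 20 moved and 0 reversed. The cause was not tested unless stated. The share of mesenchymal-like cells (cKO minus WT, -21.9 points) was -18.9 with no cell filter, -16.7 with a stricter filter, -10.8 at resolution 1.0, -16.4 for cells with a Prrx1 UMI and -2.93 with at least 20000 UMIs, always lower in cKO. The pre-osteoblast-like difference (13.8 points) was 3.25 with no cell filter, 1.80 with a stricter filter, 7.24 with at least 20000 UMIs and 16.2 without its markers in the re-clustering, and reversed to -0.31 at resolution 1.0 and -0.37 with a Prrx1 UMI, both intervals including 0. The G2 or M phase difference (-16.8 points) was -12.6 at resolution 1.0, -10.1 with a Prrx1 UMI, -0.58 with at least 20000 UMIs, -8.41 with at least 5 genes, and 0.0542 without thinning. The Slc31a1 ratio (0.338) was 0.403 with a Prrx1 UMI. The complex IV median (0.06) was 0.0804 without mitochondrial and ribosomal genes in the total and 0.0859 after scaling by the median ratio; both scalings shift every gene. The log2 ratio of Prrx1 (-0.02) turned to 0.0223 with cells weighted equally and to 0.00155 and 0.00729 under those scalings. The osteoblast and stromal progenitor medians stayed below 0 and the copper median above 0 under every alternative run. Depth limited lists with few members at 10 CPM and the shallow cells that thinning left out.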

Other observations

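Macrophage-like cells, which made up 36.8% of WT and 48.0% of cKO cells, also differed between the libraries. All 16 measured antioxidant genes were higher in cKO, with a median log2 ratio of 0.38, among them the glutathione synthesis gene Gclm (149 CPM and 260 CPM, ratio 1.74, 1.67 to 1.81), Srxn1 (1.6) and Hmox1 (1.44). Of the BMP response list, Id1 (2.35, 2.21 to 2.5), Smad6 (2.17), Id3 (2.12), Smad7 (1.72) and Id2 (1.53) were higher, and Bmpr2 had 0.942. S phase genes had a median of 0.14 at percentile 99.96, with 18 of 24 higher, including Pcna (1.24) and Rrm2 (1.30), and adipocyte genes 0.17, with Cebpb (1.63) and Cd36 (1.53) higher and Apoe (0.726) lower. Endoplasmic reticulum stress genes had 0.13 at percentile 99.5. Collagen matrix genes, which are strongest in mesenchymal-like cells, had a median of -0.17 there. Markers of other cell types were also higher in cKO within this class: neutrophil markers had a median of 0.36 (7 of 8 higher) and osteoclast markers 0.81 (3 of 3 higher; Acp5 1.88, Ctsk 1.83). The macrophage genes named here outside the mesenchymal rule were chosen after their values were seen.

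The tests below were chosen after the result was seen, except those of the summed pre-osteoblast markers and of a mixture of intact and empty cells, which were set before. WT held many more mesenchymal-like cells under 20000 UMIs, 26.78% of its cells against 5.32%, while unnamed cluster 7, of low depth and nearest to mesenchymal by its markers, held 2.15% of WT and 7.33% of cKO cells. Droplets with free RNA only cannot be told apart here. The test used 50 mesenchymal and 11 macrophage genes, chosen in the cKO library, that had served neither for clustering nor for naming. Their ratio of mesenchymal to macrophage UMIs was 46.6 in the WT mesenchymal-like cells under 20000 UMIs. It was 1.53 in T or NK cell-like, 6.55 in neutrophil-like and 48.5 in endothelial-like cells, and 46.6 is 0.9607 times the last. Only the macrophage genes had been required to be low in these comparison classes. A class's own expression of the mesenchymal genes could raise its ratio, so the endothelial-like value need not measure free RNA. The outcome depends on which class stands for free RNA. The genes and classes of this test were revised after earlier forms of it, which used T or NK cell-like cells alone and argued against free RNA, had been seen. Cells that leaked cytoplasm cannot be told apart here. In WT the mitochondrial share was 1.263 times that of deeper cells (4.21% against 3.34%), the direction leakage predicts, and cells above 15% had been removed. Malat1, a nuclear RNA whose share leakage would raise, went the other way in WT. It had 11658.5 CPM in cells under 20000 UMIs and 12596.3 CPM in deeper cells. In cKO these levels were 13573.7 and 9531.54 CPM. A cell state that depends on the genotype cannot be told apart with 1 library per group; median depth in other classes was 26243 UMIs in WT and 26078 in cKO for endothelial-like, 9204 and 7681 for macrophage-like and 6857 and 8948 for neutrophil-like cells.

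Slc31a1 UMIs remained in cKO mesenchymal-like cells at 14.3 CPM. Free RNA from macrophages would give 1.24 CPM, 8.62% of that level, from the 1.71% of their own level that 17 macrophage markers reached there. A mixture of cells with an intact gene and cells with none, at the same mean, would leave 80.5% of cells (78.4 to 82.6) without a UMI at 20000 UMIs, and 75.95% (73.4 to 78.4) had none, against 74.8% for 1 common level; the intervals nearly touch, so this argues against such a mixture only narrowly. A transcript from the recombined gene that still carries its 3' end stays open, as the floxed exons are not given in the sources used here.

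BMP response, antioxidant and immediate early lists were higher in cKO in both mesenchymal-like and macrophage-like cells. Free RNA of mesenchymal-like cells is argued against for the 24 members whose level was higher in macrophage-like than in mesenchymal-like cells. These had a median of 0.4106 in macrophage-like cells, 22 of them higher, against -0.11 to 0.08 for random lists. The lists were picked because they were higher in these cells, so the random lists add little. Most of the 24 were antioxidant genes, and Id1 and Id2 were the only BMP response genes. Atf3 (0.810) and Jun (0.784), both immediate early genes, were lower. Id3, Smad6 and Smad7 were not covered. A difference between the 2 cultures that does not follow the genotype (antioxidant median 0.3781 in macrophage-like cells) and an effect of cKO stromal cells on macrophages beside them cannot be told apart with 1 library per group.

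The hypothesis that cKO held more cells with a high summed level of pre-osteoblast markers was tested without clusters. In mesenchymal-like cells thinned to 20000 UMIs, the threshold was the WT 90th percentile of 21 summed markers without Spp1, 54.9 UMIs. This definition fixes the WT share at about 10.0%. Above the threshold lay 169 of 1682 WT cells (10.0%) and 102 of 1135 cKO cells (8.987%, 7.39 to 10.8). The median sums over all these cells were 23 and 24 UMIs. No excess of cells above the threshold was detectable. Among the same cells the pre-osteoblast-like cluster held more, 311 in WT (18.5%) and 292 in cKO (25.7%), so many of its cells lay below the threshold. The test therefore cannot decide whether the cluster share differs.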
